A study of Mus musculus with 2 samples.

How the data were processed

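H3K27me3 ChIP-seq peak lists were available for 2 biological replicates of newborn mouse stomach (postnatal day 0), each a pool of both sexes, 15 animals in replicate 1 and a number not given for replicate 2. Per the labels, both libraries used DNA of the same size range and the assembly was mm10. Beside the replicates' own lists, the authors deposited a pooled list and a replicated list for the whole series, so 4 peak lists were used. Per the descriptions deposited with the files, peaks of each replicate were called on its alignments with 2 control files, the pooled list was called on the alignments of both replicates with the same controls, and the replicated list was derived from these lists. The aligner, the peak caller, their versions and the rule for calling a peak replicated are not given in the sources used here. All 6178 replicated peaks were found in the pooled list with the same name and position.

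Each peak carried the signal value given by the authors' peak caller, a measure of enrichment that is never negative, deposited in narrowPeak format. Each peak also carried a −log10 p and a −log10 q from the authors' caller, as deposited. These are the peaks' own values and were used only to describe, rank or filter peaks within a list. Values from the pooled and replicated lists are the authors' pooled values and have no SD or n. Peak thresholds were lenient: 5.56% of replicate 1 peaks, 8.06% of replicate 2 peaks, 35.9% of pooled peaks and 65.3% of replicated peaks had q of at most 0.05. Peak lists give no read counts, so the depth per sample is unknown and no interval on read depth could be given. A gene or region without a peak was not detected at that depth, which does not show that the mark is absent. Intervals and upper limits cover counting error only. The labels call the samples biological replicates from pools, but with 2 of them no test between replicates has power, and spread is given as SD.

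Protein-coding genes were taken from GENCODE release M21 (GRCm38/mm10), the same build as the peaks, and CpG dinucleotides were counted in the RefSeq GRCm38 assembly. No peak lay past the end of its chromosome. Genes on chromosomes 1 to 19 and X entered (21755), since the Y chromosome carried no peak. Peaks on unplaced scaffolds (4 in replicate 1 and 1 in each other list) were left out of gene and location counts. A gene was called marked where at least 1 bp of a peak lay within 1000 bp of its 5′ end, and the highest signal of the peaks there was taken as its signal. One list member, Cblif, was matched under the annotation's older name Gif. Overlaps were computed by own interval code in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, tested against direct enumeration, in place of bedtools. Figures were drawn with matplotlib 3.10.9. On simulated data with peaks placed at the promoters of 1015 of the 21755 genes, the gene calling step recovered 100% of them. These peaks lay inside the window of a call, so this checks the code and not how well marked genes are detected.

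Shares of one replicate's peaks that overlap the other's have exact (Clopper-Pearson) 95% intervals and were compared with 100 circular shifts of one list within each chromosome (seed 1). Location was compared with shifts of the same kind. Gene lists were tested against all other protein-coding genes with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over 15 lists, at an adjusted p of 0.05. Where no member was marked, the upper limit is 3 genes of the list's members. The random lists matched on CpG were drawn 10000 times from 20 bins of promoter CpG count, with two-sided p. Domains were made by merging peaks within 3 kb. Hox cluster coverage ran from the first to the last gene. No correlation across samples was computed, and there was no second group to compare.

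The gene lists, the tests and most other settings were fixed before the data were examined. The lists were Hox cluster genes, stomach transcription factors, gastric epithelial products, intestinal, pancreatic and hepatic genes, other foregut regulators, neural transcription factors, muscle, heart and limb regulators, enteric nervous system genes, smooth muscle and pacemaker genes, blood and immune genes, Wnt, Fgf, Bmp and Hedgehog ligands, housekeeping genes, and olfactory and vomeronasal receptor genes. The rule for named genes, fixed at the same time, took a set of anchor genes whatever their call, up to 3 marked members per list with the highest signal, all marked members of a list with fewer than 3, and the 10 genes with the most covered bases over the gene body and 2 kb on each side. Some genes that this rule takes are not reported here. Other genes named in the Results, among them Cdx1, Hoxd13, Wnt7b and Wnt9b, were chosen after the calls were seen. The other settings fixed then were windows of 500 bp, 2.5 kb or the gene body, at least 200 bp covered, the pooled list, peaks with −log10 p of at least 5, each replicate's own list, stricter overlaps, CpG-matched lists and genes counted once per 100 kb bin. Peaks overlapping both replicates and every annotated transcript start were added after seeing the data.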

Results

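Trimethylation of histone H3 at lysine 27 (H3K27me3), the repressive chromatin mark laid down by Polycomb group proteins, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of newborn mice. The samples formed a single group of 2 biological replicates at postnatal day 0, each made from pooled stomachs of both sexes. Replicate 1 was pooled from 15 mice, and the number of mice behind replicate 2 is not given in the sources used here. Each replicate had its own peak list, with 16131 peaks covering 4.08 Mb in replicate 1 and 13265 peaks covering 4.58 Mb in replicate 2. The authors also deposited a list called on both replicates pooled (13697 peaks, 5.16 Mb) and a subset of it that they named replicated (6178 peaks, 3.25 Mb). The lists carry no read counts, so the sequencing depth is unknown, and the intervals printed here cover only the counting of peaks. With a single group there was no contrast between conditions. The comparisons were between the replicates, between gene groups and between parts of the genome.

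In the newborn stomach, replicated H3K27me3 peaks lay within 1 kb of the 5′ end of 1164 of 21755 protein-coding genes (5.35%), which are called marked genes here. The highest shares were in neural transcription factors, with 38 of 39 marked, Hox cluster genes (30 of 39), regulators of muscle, heart and limb (16 of 24), pancreatic genes (11 of 19) and regulators of other foregut organs (8 of 14). The lists were not tested against each other. None of 24 housekeeping genes, 22 products of the gastric epithelium, 18 blood and immune genes or 15 smooth muscle and pacemaker genes was marked. Of the 15 gene lists tested, 9 were marked more often than all other genes, 1 was marked less often and 5 did not pass the threshold (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the 15 lists). The replicates' own lists marked 1463 and 1668 genes, or 1566 ± 145 (SD, n = 2), and the pooled list marked 1770. Signals and their order at genes are those of the replicated list unless stated, and the order can differ in either replicate. Counting genes once per 100 kb bin lowered the folds of all 9 lists by over 1.5 times, for example from 18.8 to 10.3 for neural transcription factors. A list bin counted as marked where a list member was marked, and a bin of other genes where any gene was. The stomach factor, intestinal, pancreatic, foregut and enteric lists kept the same counts both ways, for example 11 of 19 for pancreatic genes. Their whole drop follows from the bins of other genes. Neural factors went from 38 of 39 to 35 of 36, and Hox genes from 30 of 39 to 7 of 9. Muscle, heart and limb regulators went from 16 of 24 to 16 of 23, and ligands from 19 of 38 to 15 of 33. Genes are not independent replicates, so each p-value describes these peak lists and not the variation between animals.

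**Figure D1:**
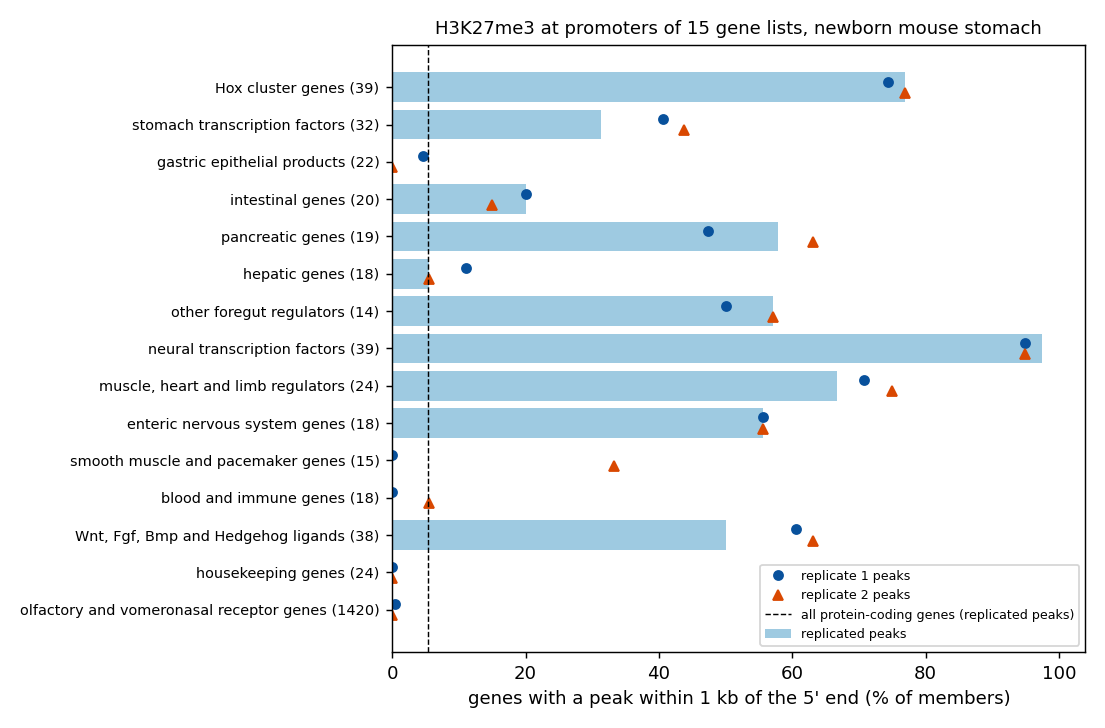
Share of the genes in each of 15 lists with an H3K27me3 peak within 1 kb of the 5′ end (horizontal axis, percent of members; number of members in brackets). Bars show the replicated peaks, circles replicate 1, triangles replicate 2, and the dashed line the 5.35% of all protein-coding genes marked by replicated peaks; neural transcription factors and Hox cluster genes reached 97.4% and 76.9%, and smooth muscle and pacemaker genes had calls in replicate 2 alone.

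Hox genes, which set positional identity along the body axis, carried the longest stretches of the mark. By replicated peaks 30 were marked, 14.7 times the share of other genes (adjusted p = 3.31e-30, Fisher's exact test), with 29.5 ± 0.707 (SD, n = 2) marked per replicate. Neighbouring Hox genes can share peaks. Counted once per 100 kb bin, 7 of 9 bins were marked, 8.06 times the share of other bins (adjusted p = 5.14e-06, Fisher's exact test). Bins of other genes counted any marked gene, so this fold and 14.7 are not on the same footing. The Hoxd cluster (chromosome 2, 74668310 to 74765142, GRCm38/mm10) was covered by replicated peaks over 43.7% of its length, the Hoxc cluster (chromosome 15, 102921103 to 103036852) over 34.8%, the Hoxa cluster (chromosome 6, 52155590 to 52260880) over 22.9% and the Hoxb cluster (chromosome 11, 96194316 to 96368256) over 18.1%. The genome as a whole was covered over 0.123%. All 9 Hoxd genes were marked, against 8 of 9 Hoxc genes, 7 of 11 Hoxa genes and 6 of 10 Hoxb genes. The highest signals at Hox 5′ ends in the replicated list were at Hoxd10 (5.64), Hoxd1 (5.46), and Hoxc12 and Hoxd13 (5.10 each), and Hoxa13, the most posterior Hoxa gene, had a signal of 4.02. Hoxd10 had signals of 3.56 in replicate 1, where it did not lead, and 6.61 in replicate 2. The unmarked genes, among them Hoxb1, Hoxb2, Hoxb3, Hoxb5 and Hoxc4, were all in paralogue groups 1 to 5, where 9 of 15 genes were unmarked against 0 of 24 in groups 6 to 13. This division was examined after the calls were seen. The calls depend on the window. With a 2.5 kb window or every transcript start 32 of 39 Hox genes were marked, and with the gene body 33. The windows of Hoxb2, Hoxb3 and Hoxc4 held 20, 23 and 23 CpG dinucleotides, fewer than any marked Hox window (46 or more). The outermost annotated 5′ end was used for each gene, and that of Hoxc5, which was marked, lies between Hoxc10 and Hoxc9. Coverage differed between the replicates in every cluster, at 31.5% ± 13.7 for Hoxd and 17.1% ± 4.87 for Hoxa (SD, n = 2). Over all 4 clusters it was 14.4% in replicate 1 and 26.8% in replicate 2, against 28.1% in the replicated list.

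**Figure D2:**
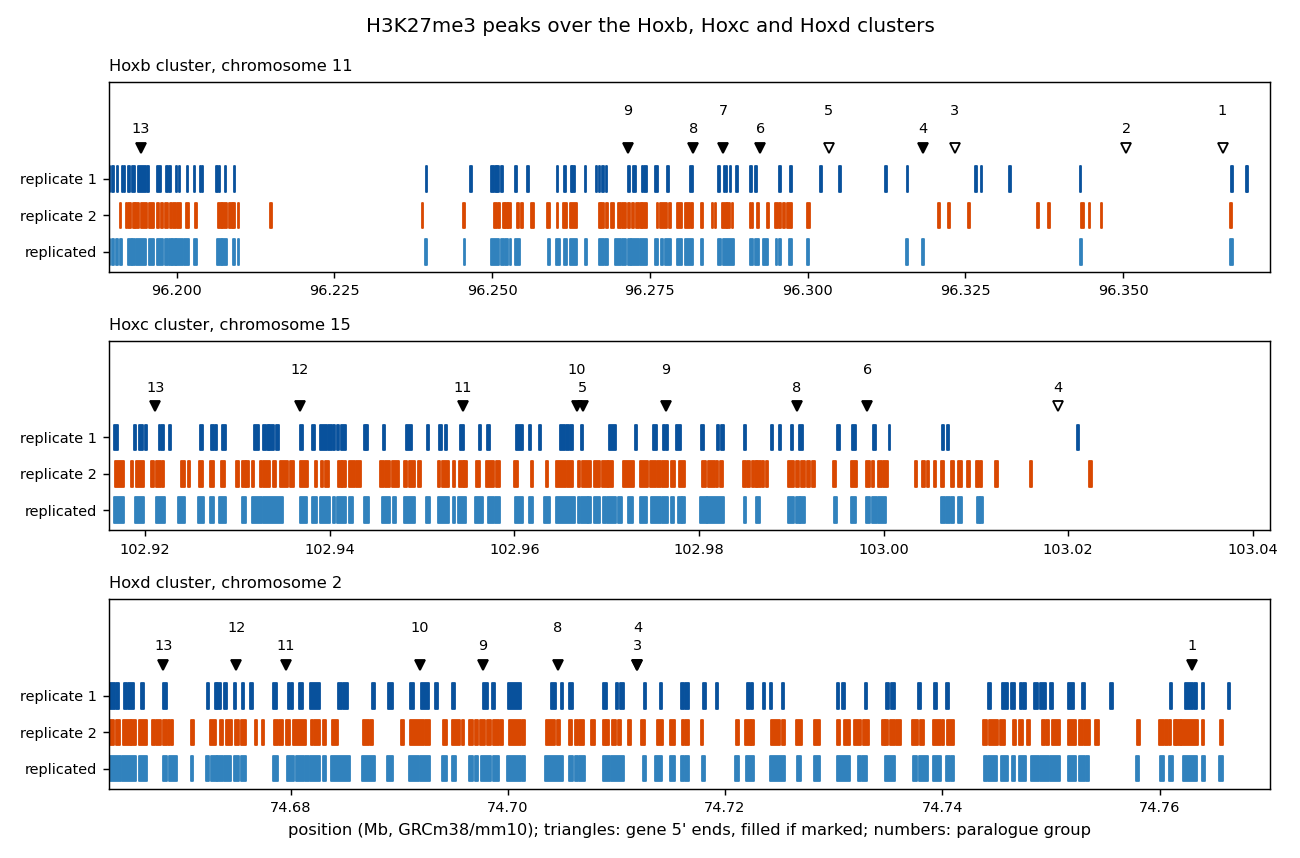
Positions of H3K27me3 peaks over the Hoxb, Hoxc and Hoxd clusters (horizontal axis, position in Mb on GRCm38/mm10; rows, the peaks of replicate 1, replicate 2 and the replicated list). Triangles stand for gene 5′ ends with their paralogue number, filled where marked; the 5 open triangles all belong to groups 1 to 5.

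Transcription factors of the nervous system were the most completely marked list, with 38 of 39 members against 5.19% of other genes, 18.8 times the share (adjusted p = 1.49e-46, Fisher's exact test) and 37 members called in each replicate. The exception was Tbr1, a cortical T-box factor, named here after the calls were seen, which was called in replicate 2 and in the pooled list. Olig2, the oligodendrocyte and motor neuron factor, had the highest signal at a 5′ end among the listed neural genes (6.90), followed by Tlx3 (5.64) and Dlx1 (5.10). Pax6, an eye and brain regulator (chromosome 2, 105668900 to 105697364), had a signal of 4.74 at its 5′ end and replicated peaks over 31.7% of its gene body with 2 kb on each side. Among the 10 genes with the most covered bases over the gene body and 2 kb flanks were Lhx2 (13835 bp), Zic4 (13654 bp), Pax3 (12111 bp), Skor1 (11599 bp) and Lmx1b (10546 bp), and in Skor1 the covered part reached 78.4%. Hoxc5 (18730 bp) and Hoxd3 (16679 bp) led this ranking, but their annotated spans run over neighbouring genes. That of Hoxc5 takes in the 5′ ends of Hoxc9 and other Hoxc genes, and that of Hoxd3 those of Hoxd4 and Gm28230. Gm28230, annotated inside the Hoxd cluster, had 11293 bp. Gm20388 and Fgfr2 also ranked among the 10, with 14723 and 14152 bp, but their annotated spans run over megabases, their covered shares were 0.332% and 0.477%, and their 5′ ends carried no peak in any list.

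Lists of genes from neighbouring endodermal organs were marked in part. Of the pancreatic genes 11 of 19 were marked, 10.9 times the share of other genes (adjusted p = 1.25e-09, Fisher's exact test), with 9 in replicate 1 and 12 in replicate 2 (7.08 times without replicate 2 and 6.02 times by 100 kb bins). They included Ptf1a (signal 4.92), which specifies pancreatic progenitors, Insm1 (4.92) and Nkx2-2 (4.50), both endocrine factors, and Pdx1 (4.02), which is also active in the distal stomach. Among regulators of thyroid, lung, thymus and other foregut derivatives 8 of 14 were marked, 10.7 times the share of other genes (adjusted p = 2.77e-07, Fisher's exact test), with 7 and 8 in the replicates (7.05 times in the pooled list). Hhex (5.28), Pax8 (4.56) and Pax9 (4.56) had the highest signals, and Nkx2-1, the thyroid and lung factor, had 3.29. In the intestinal list 4 of 20 genes were marked (3.75 times; adjusted p = 0.0298, Fisher's exact test), with 4 and 3 in the replicates. They included Cdx2 (5.10) and Cdx1 (3.47), which set intestinal identity, and Atoh1 (3.84, with 2.47 in replicate 1 and 3.73 in replicate 2), a secretory lineage factor. The 16 unmarked members included digestive enzymes, mucins and transporters. This last call was lost under 9 of 12 alternative settings, among them each replicate's own list (Fisher's exact test, adjusted p = 0.265 without replicate 1 and 0.0623 without replicate 2). Of 18 hepatic genes 1 was marked, Prox1 (2.31, against 4.07 in replicate 1, 3.63 in replicate 2 and 3.47 in the pooled list), an early liver and lymphatic factor, and the list did not differ from other genes (1.04 times; adjusted p = 1, Fisher's exact test). Alb, the serum albumin gene, had no peak at its 5′ end in any list. Over these 4 organ lists, genes for enzymes, hormones and other products had a median of 20 CpG dinucleotides within 1 kb of the 5′ end, and regulators 86.

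Genes of the stomach itself were tested as a list of transcription factors and a list of epithelial products, which were not compared with each other. The pools were stomachs of mixed cell types, so a peak does not tell which cells carry the mark at a gene. Of 32 transcription factors known from stomach development 10 were marked, 5.88 times the share of other genes (adjusted p = 6.75e-06, Fisher's exact test), with 13.5 ± 0.707 marked per replicate (SD, n = 2). The highest signals were at Nkx2-3 (5.10) and Nkx3-2 (4.20), factors of the gut mesenchyme, followed by Foxl1, also mesenchymal, and Grhl2, an epithelial factor (4.02 each), and Gata4, an endodermal and cardiac factor, had 3.11. The other marked members, named like Grhl2 after the calls were seen, were Foxa3, Foxf1, Gata5, Hlx and Tcf21. Barx1, a factor of the stomach mesenchyme, was called in both replicates and in the pooled list and was still absent from the replicated list. Sox2, which marks the anterior stomach epithelium, was called in replicate 2 and in the pooled list but not in replicate 1 or the replicated list. None of the 22 genes for gastric epithelial products was marked, which allows a share of up to 13.6% and did not differ from other genes (adjusted p = 0.735, Fisher's exact test). Atp4a, a subunit of the proton pump of parietal cells, and Muc5ac, the mucin of surface cells, had no peak at the 5′ end in any list. One member, the somatostatin gene Sst, named after the calls were seen, was called in replicate 1 alone.

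Regulators of muscle, heart and limb were marked in 16 of 24 cases, 12.6 times the share of other genes (adjusted p = 7.50e-15, Fisher's exact test), with 17.5 ± 0.707 per replicate (SD, n = 2). Alx1 and Tbx20 (5.10 each) had the highest signals, followed by Alx4 and the skeletal muscle regulator Myod1 (4.38 each), and the heart regulator Nkx2-5 was marked with 3.65. Enteric nervous system genes were marked in 10 of 18 cases, 10.5 times the share of other genes (adjusted p = 1.17e-08, Fisher's exact test), with 10 in each replicate. Enteric neurons and glia are part of the stomach wall, and here too the cells that carry the mark are unknown. Tlx2 (6.18), Tubb3 (5.46) and Elavl3 (5.28) led this list. Of 38 Wnt, Fgf, Bmp and Hedgehog ligands 19 were marked, 9.48 times the share of other genes (adjusted p = 2.40e-14, Fisher's exact test), with 23.5 ± 0.707 per replicate (SD, n = 2). Wnt1 and Wnt7a (4.92 each) had the highest signals, followed by Wnt10b, Wnt7b and Wnt9b (4.74 each). Shh, an endodermal signal, was called at its 5′ end in replicate 1 and in the pooled list but not in replicate 2 or the replicated list, although replicated peaks covered 1981 bp (13.7%) of its gene body and 2 kb flanks. Cdkn2a, a cell cycle inhibitor and a classical Polycomb target outside the lists, was marked with a signal of 4.38.

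Smooth muscle and pacemaker genes gave different calls in the replicates. None of 15 was marked by replicated peaks, which allows a share of up to 20%, and the list did not differ from other genes (adjusted p = 1, Fisher's exact test). Replicate 1 also marked none, while replicate 2 marked 5 at their 5′ ends, which were Myh11, Cnn1, Des, Myocd and Kit, named apart from Myh11 after the calls were seen. Myh11 had a replicate 2 signal of 3.63, Myocd 3.25, Cnn1 3.17, and Des and Kit 2.54 each. The median over all replicate 2 peaks was 3.36 and the lowest 2.09. Cnn1 and Des were not called in the pooled list. In replicate 2 alone the list was marked 4.36 times as often as other genes (adjusted p = 0.00618, Fisher's exact test), but the difference between the replicates could not be tested at 0.05, since 0.0625 is the smallest two-sided p that 5 genes against 0 can give in an exact McNemar test. Of 18 blood and immune genes none was marked (up to 16.7%; adjusted p = 0.735, Fisher's exact test), with 0 and 1 calls in the replicates and 1 in the pooled list. Ptprc, the pan-leukocyte gene, had no peak at its 5′ end in any list. None of 24 housekeeping genes was marked (up to 12.5%; adjusted p = 0.735, Fisher's exact test), Actb included, and neither replicate called any. Olfactory and vomeronasal receptor genes, silent outside sensory epithelia, were marked in 0 of 1420 cases, which allows up to 0.211%, against 5.72% of other genes (adjusted p = 8.87e-35, Fisher's exact test), with 5 and 0 calls in the replicates. Against random gene lists with the same CpG counts, which had 0.889 marked genes on average, this shortfall was not past the threshold (adjusted p = 0.92, permutation test with 10000 lists).

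Marked genes had CpG-rich 5′ ends. The median count of CpG dinucleotides within 1 kb on each side of the 5′ end was 101 for the 1164 marked genes and 59 for the 20591 others. Among 20 equal bins of genes ordered by CpG count, the share marked was 0% in the lowest bin and 12.3% in each of the highest 2 bins. Against random gene lists matched on these bins, the 9 lists marked more often still had 3.82 to 11.4 times the marked genes of the random lists. Of these, intestinal genes had 7.85 times and the highest adjusted p, 0.003 (permutation test with 10000 lists). For the 5 lists with no marked gene the random lists held 0.200 to 1.83 marked genes on average, so a count of 0 carries little information there.

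**Figure D3:**
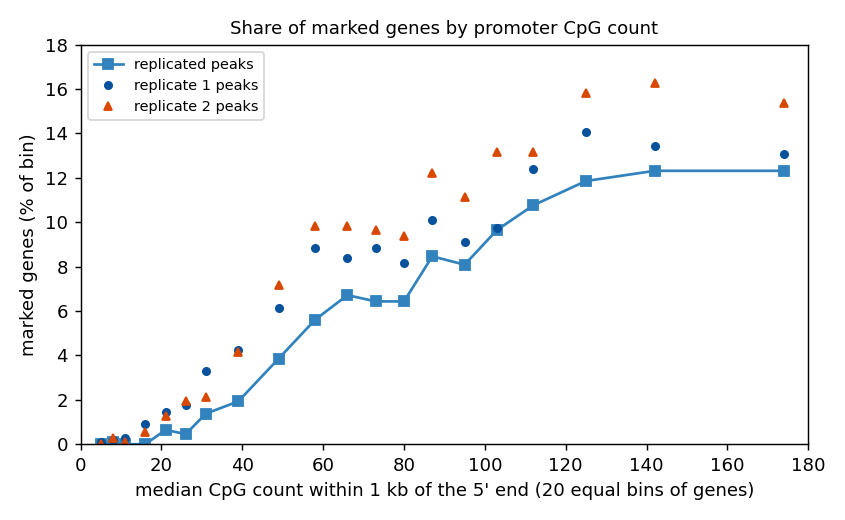
Share of protein-coding genes with an H3K27me3 peak within 1 kb of the 5′ end (vertical axis, percent) against the median CpG count of that window (horizontal axis) in 20 equal bins of genes. Squares joined by a line show replicated peaks, circles replicate 1 and triangles replicate 2; the replicated share went from 0% in the lowest bin to 12.3% in the highest.

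Replicated peaks were concentrated at gene 5′ ends. Windows of 1 kb on each side of protein-coding 5′ ends held 24.4% of the covered bases, against 1.64% on average for 100 circular shifts of the peaks within their chromosomes (14.8 times). Exons held 15.3% against 3.55% after shifting, introns 26.8% against 37.0%, and sequence between genes 33.5% against 57.8%. Each difference had p = 0.0198 in this permutation test, the smallest two-sided value that 100 shifts can give. The enrichment at 5′ ends was 12.6 times in replicate 2 and 8.18 times in replicate 1. After merging peaks within 3 kb of each other, the replicated list formed 2258 domains with a median length of 764.5 bp, of which 140 were at least 10 kb long. The longest, 108097 bp on chromosome 2 (74645371 to 74753467), ran from Evx2 across 8 Hoxd genes and held 79 peaks. The next were 74095 bp at the Hoxc cluster and 70949 bp at the Hoxa cluster.

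The replicates shared far more peaks than chance gave, though most peaks of either list had no partner in the other. Of the 16131 peaks of replicate 1, 3804 overlapped a replicate 2 peak by at least 1 bp (23.6%, exact 95% interval 22.9 to 24.2), and 3660 of the 13265 peaks of replicate 2 overlapped replicate 1 (27.6%, 26.8 to 28.4). Circular shifts gave 0.312% and 0.395% on average (permutation p = 0.0099 in each direction, the smallest one-sided value that 100 shifts can give). The shared bases were 0.865 Mb of 7.79 Mb in either list, a Jaccard index of 0.111. Peaks with higher signal more often overlapped a peak of the other replicate's full list. When each list was divided into 3 equal groups by signal, 36.4%, 19.7% and 14.6% of replicate 1 peaks were shared from the highest group to the lowest, and 45.4%, 22.7% and 14.7% of replicate 2 peaks. Across the 3804 shared peaks, signal values correlated weakly (Spearman rho = 0.141, Pearson r = 0.157 on log values), with no p-value because peaks are not independent. The 10 most frequent signal values held 85.9% of replicate 1 peaks and 76.0% of replicate 2 peaks. With an overlap of 50% of both peaks required, the shared percentages were 9.04% and 10.99% and rho was 0.207. Among peaks with a −log10 p of at least 5 rho was 0.0656, and with peaks merged within 3 kb 14.5% of replicate 1 and 25.8% of replicate 2 were shared.

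Counted by gene, the shares called in both replicates were larger. Both replicates called 961 genes, or 65.7% of replicate 1's genes and 57.6% of replicate 2's, where independent lists would share 112. This excess and that of shared peaks over circular shifts (75.5 and 69.8 times) have different baselines and upper bounds, so their sizes cannot be compared. Of the 1164 genes marked by replicated peaks, 864 (74.2%) were called in both replicates. The replicated list held 45.1% of the pooled peaks, with a median width of 423 bp against 226 bp for the pooled peaks left out, and a median −log10 p of 5.85 against 3.63. Of its 6178 peaks, 3310 (53.6%) overlapped a peak of both replicates' own lists, 2562 (41.5%) a peak of one alone and 306 (4.95%) a peak of neither. Restricting the calls to the 3310 peaks, a choice made after seeing the data, left 804 marked genes.

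Replicated peaks were sparse on the X chromosome. They covered 37.9 bp per Mb of X against 1317 bp per Mb of the autosomes, a ratio of 0.0288, with 19 peaks on X. Chromosome 19 had the densest coverage at 2638 bp per Mb, and the Y chromosome had no peak in any list. The X to autosome ratio was 0.356 in replicate 1 (434 X-linked peaks) and 0.0801 in replicate 2 (98 peaks), a spread between replicates wider than the replicated value itself. In the pooled list the ratio was 0.063, and counted as peaks per Mb in place of bases it was 0.0444 in the replicated list. Pools of both sexes hold fewer copies of X than of an autosome, so equal coverage is not the baseline. Unshared replicate 1 peaks, once shifted, held 0.581 CpG per 100 bp on X and 0.828 over all chromosomes. Few called peaks do not show that the mark itself is sparse on X.

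**Figure D4:**
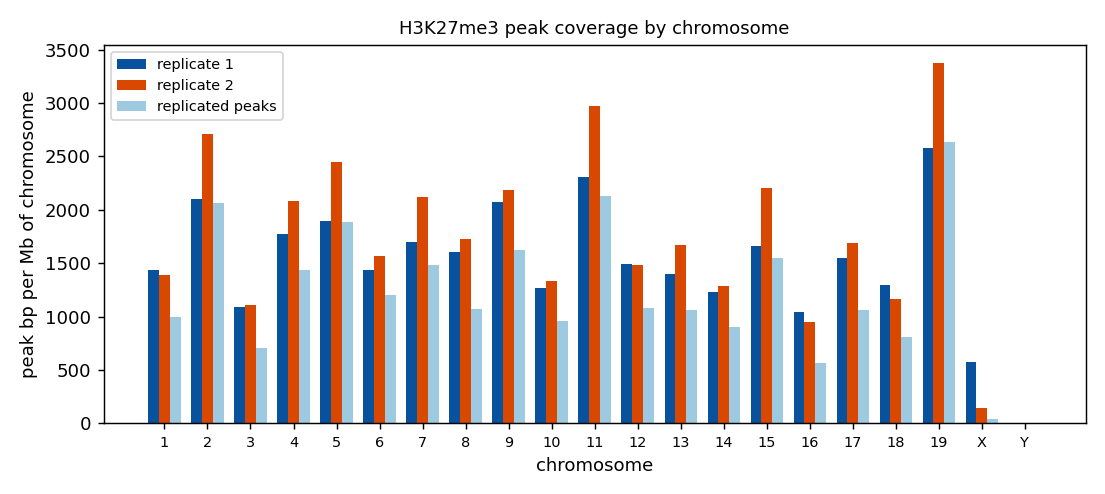
Bases covered by H3K27me3 peaks per Mb of each chromosome (vertical axis) for replicate 1, replicate 2 and the replicated list. The X chromosome has 575, 148 and 37.9 bp per Mb, lower than every autosome in each list, and the Y chromosome has none.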

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

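Of these alternatives, peaks overlapping both replicates' lists and every transcript start were chosen only after the data were seen. In 203 of 228 recomputations the direction and the side of the threshold were kept, or a value without a test stayed within the spread or interval of its main value, or a count of genes within 1.5 times of it. This total includes outcomes with little room to change. The gastric product, blood and housekeeping lists, with no gene marked by replicated peaks, were rated the same in all 12 settings each. Replicate 1 overlap was rated the same as it fell from 23.6% to 9.04%, since its p stayed at the smallest value of 100 shifts. The number of lists marked more often than other genes was 8 or 9 in every setting, with all 9 lists but the intestinal one past the threshold throughout; without replicate 1 the ninth list was that of smooth muscle and pacemaker genes. No paired analysis was possible because there was a single group. Peak lists carry no depth, so its effect could not be examined.

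Intestinal genes lost their call at folds of 3.55 (500 bp window), 3.19 (2.5 kb window), 2.63 (gene body), 3.01 (200 bp covered), 2.46 (pooled list), 3.16 (every transcript start), 2.07 (1 value per 100 kb bin) and 1.96 to 2.98 with either replicate left out. Hepatic genes, never past the threshold, went from 1.04 to 3.63 (CpG-matched lists), 1.504 (peaks overlapping both replicates' lists), 0 (500 bp window and −log10 p of at least 5), 0.885 (2.5 kb), 0.729 (gene body), 0.683 (pooled list), 0.877 (every transcript start), 0.687 (100 kb bins) and 0.724 to 1.65 without either replicate. Smooth muscle and pacemaker genes went from 0 to 1.06 (2.5 kb), 2.46 (pooled list) and 0 to 4.36 without either replicate. The olfactory and vomeronasal shortfall, at a fold of 0, was lost against CpG-matched lists, which hold few marked genes themselves. The pooled list marked 1770 genes in place of 1164, and the other settings 804 to 1668. Signal correlation moved from 0.141 to 0.207 with an overlap of 50% of both peaks and to 0.0656 at −log10 p of at least 5. Hox cluster coverage was 14.4% to 26.8% without either replicate, against 28.1%. By 100 kb bins the intestinal list kept 4 of 20 marked, while bins of other genes counted any marked gene, which lowers the fold. Apart from this and the CpG-matched lists, the cause of these changes was not tested.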

Other observations

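The tests of gene families, of the position of Hox genes, of pooled calls at Hox genes and of the Hox genes with the fewest CpG, and the division into regulators and products, were chosen only after the results were seen.

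Some ion channel and receptor families outside the fixed lists carried the mark, while others did not pass the threshold. When protein-coding genes were grouped by the first 3 letters of their symbols, 20 of the 372 families with at least 10 members were marked more often than other genes and 3 less often (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over 372 families). Symbols that begin with Kcn, mostly potassium channel genes, were marked in 29 of 94 cases against 5.24% of other genes (adjusted p = 4.56e-13, Fisher's exact test), with 30 called in replicate 1 and 37 in replicate 2. Families that begin with Gri (ionotropic glutamate receptors among them; 7 of 24, adjusted p = 0.00473), Adr (adrenergic receptors among them; 5 of 10, 0.00232) and Cac (calcium channels among them; 7 of 31, 0.0205) were also marked more often by the same exact test. Each of these 3 families had 4 or more calls in either replicate. Families that begin with Scn (sodium channels among them; 3 of 18, adjusted p = 0.509), Gab (GABA receptors among them; 5 of 30, 0.204), Chr (nicotinic and muscarinic receptors among them; 3 of 25, 0.77), Glr (0 of 10) and Clc (0 of 18) did not pass the threshold of the same exact test, and the channels and receptors were not tested as one group. CpG content was not matched between families and other genes.

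Families of developmental transcription factors were marked in part, with 13 of 14 Nkx genes (adjusted p = 4.56e-14, Fisher's exact test), 19 of 46 Fox genes (4.65e-11), 8 of 19 Sox genes (1.09e-04) and 7 of 16 Pou genes (2.63e-04). These tests reuse genes of the fixed lists, and outside the lists 6 of 7 Nkx, 13 of 36 Fox, 7 of 16 Sox and 5 of 14 Pou genes were marked. Foxb1 (6.72), Sox18 (5.10), Nkx1-1 (4.92), and Pou3f1 and Pou3f2 (4.56 each) had the highest signals of the replicated list within their own families outside the fixed lists. Zinc finger genes that begin with Zfp went the other way, with 3 of 397 marked (0.756%; adjusted p = 5.51e-05, Fisher's exact test), and 11 and 4 called in the replicates. Among noncoding genes, marked ones were 121 of 5305 lincRNA genes (2.28%) and 134 of 2958 antisense genes (4.53%), and the shares among those more than 2 kb from a protein-coding 5′ end were 1.56% and 2.34%. Marked noncoding genes included Hotair and Hottip, which lie in the Hoxc and Hoxa clusters, Dlx6os1 and Emx2os.

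The unmarked Hox genes had a mean paralogue number of 3 against 8.37 for marked genes, but the test of this (permutation p = 3e-05, calls shuffled within clusters) restates the division already seen and treats neighbours that can share peaks as independent, so it decides nothing. Low CpG density as the cause for the whole set is argued against by the median CpG count of the 9 unmarked windows, 80, above the lower quartile of 71 for marked windows, although 3 of them (Hoxb2, Hoxb3 and Hoxc4) had fewer CpG than any marked Hox window, and for these 3 CpG density and position cannot be told apart. Weak peaks lost from the replicated list as the whole cause are argued against by the pooled list, which had peaks at 2 of the 9, Hoxb1 and Hoxb3, and over all lists together 3 of the 9 had a peak. A candidate explanation for the rest is that anterior Hox genes are active in stomach tissue, which these peak lists cannot test. Some of the unmarked calls also depend on the window, since a 2.5 kb window or every transcript start marked 32 of 39 Hox genes. Hoxb4, Hoxc5, Hoxd1, Hoxd3 and Hoxd4 were among those marked despite their group, Hoxb4 in the pooled and replicated lists but in neither replicate's own list, Hoxc5 at an annotated 5′ end that lies among more posterior genes, and Hoxd3 and Hoxd4 at 5′ ends 2 bp apart, which share a window.

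Most peaks of either replicate had no partner in the other, and of 434 X-linked peaks in replicate 1 only 5 had one. Background calls scattered without regard to sequence, as the whole source, are argued against by CpG content. It was 1.69 CpG per 100 bp in the unshared peaks of replicate 1 and 2.85 in those of replicate 2. The highest of 100 circular shifts gave 0.864 and 0.905. The 429 unshared X-linked peaks of replicate 1 held 1.01 CpG per 100 bp, against at most 0.753 along the X chromosome. Background calls gathered at CpG-rich sequence would also have high CpG content, so the shifts cannot exclude these in any of the 3 sets. A mixture of background and weak marked sites may remain in each case, since the shared peaks of replicate 1 held 4.59. Depth and the callers' thresholds stay open and untested, and no biological explanation could be tested within 1 group.

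Within the intestinal, pancreatic, hepatic and foregut lists, 24 of 33 regulators were marked against 0 of 38 genes for products such as enzymes, hormones and plasma proteins (p = 7.28e-12, Fisher's exact test). Shuffling calls within 4 classes of CpG count left a difference (permutation p = 0.011), but these classes were too wide to exclude CpG density. The lowest CpG count of a marked regulator was 40, and 36 of the 38 products lay below it. Among windows at or above 40 CpG, 24 of 27 regulators and 0 of 2 products were marked, too few products to decide. Low CpG density of the product promoters and their role as products cannot be told apart here, and either may account for the pattern.

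The strongest replicated peak by −log10 p (149, signal 4.38) lay on chromosome 17 from 39843000 to 39846813, over the annotated genes CT010467.1 and Gm26917. The next (135, signal 4.02) lay from 39847855 to 39848946 on the same chromosome, over AY036118 and Gm42418 among others. Gm26917, AY036118 and Gm42418 are counted among the marked lincRNA genes. The highest signal of the replicated list, 8.97, was at a 480 bp peak overlapping Cdk8 (chromosome 5, 146261003 to 146261482). The peak at Olig2 had a higher signal than these chromosome 17 peaks, 6.90, at a much lower −log10 p of 17.9. No artefact-prone regions were filtered out here. Whether the peaks at these places reflect the mark or background of the assay was not tested. Of 7519 pooled peaks outside the replicated list, 124 (1.65%) overlapped peaks of both replicates.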
